A study of Vitis vinifera with 24 samples.

How the data were processed

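RNA from leaves of 24 samples of Vitis vinifera 'Thompson Seedless' was sequenced, and 1 table of gene expression values was deposited, with 35840 genes and 1 column per sample. The values are FPKM, fragments scaled to the length of the transcript and to the number of mapped fragments, computed by the authors before they were deposited and not pooled over replicates. The submitters' processing notes name fastp 0.20.0, HISAT2 2.1.0, SAMtools 1.9 and StringTie 2.1.3b without their role or order. The genome build, annotation, strandedness and settings are not given in the sources used here. Library preparation used a kit with a dual-mode protocol, per the labels' protocols, and how it was run is not given. Reads of near-identical genes, overlapping genes or antisense partners may have been divided between them by the authors' estimation, and this cannot be resolved from FPKM.

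Each column was assigned to its sample by its name, and each sample to 1 of 8 groups by its treatment label, with 0 columns left unused. The labels state that the replicates are biological and do not say whether they came from separate plants, so p-values measure the spread between these samples. Depth is unknown. Low values were searched for the steps that whole reads would leave: over 1911 genes above 0 and below 0.2 FPKM in both of 2 control libraries, no window of 2% held more than 1.83% of the ratios between these libraries, so reads were not recovered and no count test was run. FPKM also ties each gene to the total of its library, so a few abundant genes can shift all others. The 10 most abundant genes held 14.5 ± 0.071% of the FPKM in control (SD, n = 3), 9.67 ± 0.079% in cold and 8.41 ± 0.018% in PEG6000 leaves.

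Genes are identified by 35134 identifiers beginning with Vitvi and 706 beginning with PT_newGene. Neither kind is paired with names in the table, and 0 identifiers matched the reference table of gene names, which belongs to another assembly and was used for nothing. For that reason the 40 lists of pathway genes, cell type markers and organelle genes fixed in advance could not be matched to genes and were not tested, and shifts in the cell types of the leaf were not assessed.

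Genes with at least 1 FPKM in at least 3 libraries were kept, 20053 in all, 475 of them PT_newGene identifiers. Values were transformed to log2(FPKM + 1), and fold changes on this scale understate the change of low genes. A 2-fold change means an absolute log2 change of at least 1. Tests were made with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend of the variance on the mean) with 1 mean for each of the 8 groups and 16 residual degrees of freedom. P-values are two-sided and were adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called at an adjusted p below 0.05. There were 13 such comparisons: each single treatment against control, trehalose with a stress against that stress, the difference between these trehalose effects and that of trehalose alone (interaction), and each pair of stresses. Trehalose with each of the 3 stresses was also tested against trehalose alone in the same way. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

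Genes were named by a rule fixed before the data were examined, as were the groups, the main tests and the alternatives. Some tests in the closing parts were chosen only after the results were seen. The rule took the 5 called genes with the largest rise and the 5 with the largest fall per main comparison, with a mean of at least 5 FPKM in the higher group and no overlap between the replicates of both groups; a condition on gene descriptions could not be applied. The first 2 of each direction are printed. Absence of overlap alone arises by chance in 10% of genes with 3 libraries against 3. Comparisons that share libraries are given beside 20 simulations of unchanged groups and beside the overlap of independent lists of the same size.

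The limma step was tested on simulated values for the 20053 genes in the comparison of cold with control, with 200 genes changed by known folds. It called 27 of 50 genes changed 1.2-fold, 42 of 50 at 1.5-fold, 48 of 50 at 2-fold and 50 of 50 at 4-fold, with 7 false calls. Alternatives covered the pseudocount, the filter on low values, 3 scalings (to a common sum as for TPM, by median-of-ratios factors, and quantile normalization), the variance model, sample weights, the samples in the fit, the replicate number as a block, leaving out each library, and a 2-fold limit.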

Results

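RNA-seq was carried out on leaves of the grapevine cultivar 'Thompson Seedless', taken from self-rooted greenhouse cuttings. Leaves were untreated (control), given trehalose, exposed to low temperature (4 ℃, called cold here), NaCl or PEG6000, or given trehalose together with 1 of these 3 stresses. Trehalose is a non-reducing disaccharide of glucose, NaCl imposes salt stress, and PEG6000 is a polyethylene glycol that lowers the water potential of the medium. Each of the 8 groups held 3 biological replicates, 24 libraries in all. Treated leaves were collected at 48 h per the labels, which give no time for the control, no doses, no batch, and no order in which trehalose and stress were applied. Expression was available as FPKM, so the sequencing depth is unknown. FPKM summed to between 597567 and 637648 per library. Genes at 1 FPKM or more numbered 16970.3 ± 16.2 (SD, n = 3) in control leaves and 18311 ± 87.3 (SD, n = 3) in leaves given trehalose and PEG6000. Genes carry identifiers only, and the sources used here do not pair them with names or functions, so genes are described in groups defined by their response, with at most 2 identifiers that rose and 2 that fell per comparison.

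Replicates lay close together and the treatments far apart. Pearson correlations of log2(FPKM + 1) ranged from 0.994 to 0.997 between replicates of a group and from 0.823 to 0.989 between libraries of different groups, and 0 pairs of libraries were identical. The first principal component held 54.5% of the variance and separated the libraries kept in the cold, with and without trehalose, from control. PEG6000 libraries also lay towards the cold side of it, at 42.4 to 43.2 against -53.7 to -52.7 in control. The second held 26.9% and separated PEG6000 leaves, while leaves given trehalose with PEG6000 lay between the control and NaCl libraries on both components. They stood apart on the third component (7.88% of the variance), at 56.1 to 56.5, with all other libraries between -22.5 and 3.15. The mean distance from control, as the root mean square of the log2 differences over 20053 genes, was 1.07 for cold, 1.10 for PEG6000, 0.56 for NaCl and 0.27 for trehalose. With trehalose the same distance from control was 1.02 for cold, 0.64 for PEG6000 and 0.30 for NaCl.

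**Figure D1:**
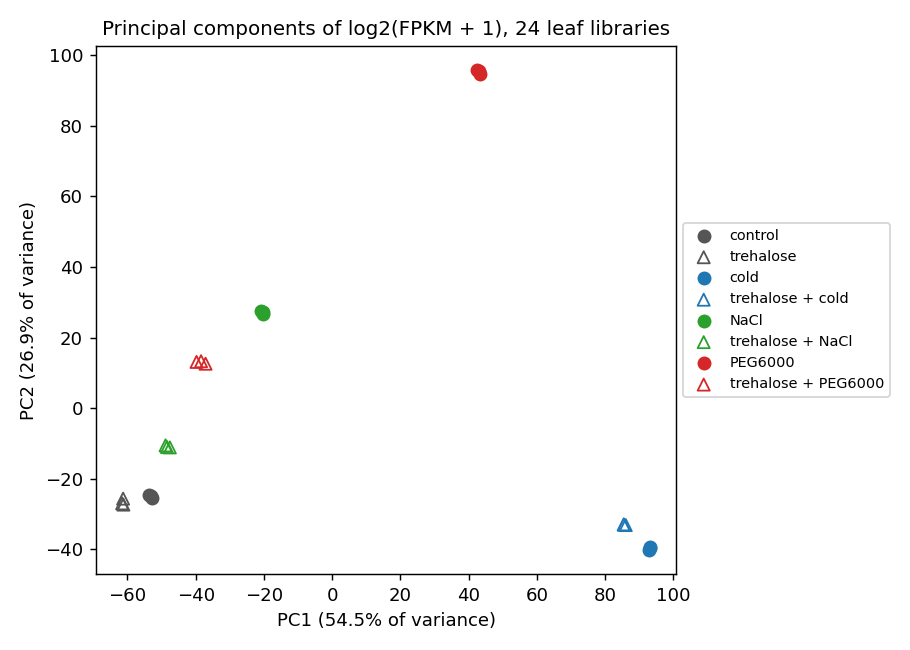
Scores of the 24 libraries on the first principal component (x axis, 54.5% of the variance) and the second (y axis, 26.9%) of log2(FPKM + 1). Filled circles are groups without trehalose and open triangles groups with it. The 3 libraries of each group overlap, cold libraries lie at the right with or without trehalose, and PEG6000 libraries stand at the top only where trehalose was not given.

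Of the 4 single treatments, cold changed the largest number of genes 2-fold, and PEG6000 the largest number 8-fold. Against control, 2360 genes rose and 2716 fell at least 2-fold in the cold. On the log2 scale used, 375 rose and 25 fell at least 8-fold in the cold, against 536 and 36 under PEG6000. Vitvi08g04419 went from 1.84 ± 0.54 to 1269 ± 11.3 FPKM (SD, n = 3), a log2 change of 8.82 (SE 0.16), and Vitvi04g01368 from 4.19 ± 0.80 to 1639.7 ± 41.7 FPKM (log2 change 8.31, SE 0.11). Vitvi03g00064 fell from 102 ± 2.8 to 2.46 ± 0.77 FPKM and Vitvi03g01350 from 31.2 ± 1.8 to 0.445 ± 0.13 FPKM, log2 changes of -4.93 (SE 0.11) and -4.48 (SE 0.08). A set of 119 genes was below 1 FPKM in every control library and at 10 FPKM or more in every cold library, and 9 genes did the reverse. In the limma test at an adjusted p below 0.05, 16744 of 20053 genes were called, 6295 higher and 10449 lower, and the adjusted p of the 4 named genes was at most 1.17e-21. The median log2 change of all genes was -0.20. More genes were also called lower than higher with TPM-like scaling (10004 and 6657) and quantile normalization (9732 and 6813), although at 2-fold quantile normalization gave 2518 higher and 2298 lower. With median-of-ratios scaling, which by construction sets the median change near 0, it was 0.01, with 8429 genes called higher and 8019 lower and, at 2-fold, 2993 higher and 1830 lower.

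Salt gave a smaller response, made up mostly of genes that rose. NaCl raised 1178 genes at least 2-fold and lowered 193. Vitvi14g02893 increased from 3.25 ± 0.27 to 139 ± 13 FPKM (SD, n = 3; log2 change 5.04, SE 0.08) and Vitvi05g00170 from 0.508 ± 0.40 to 30.3 ± 0.68 FPKM (log2 change 4.40, SE 0.12). Vitvi01g01030 fell from 13.1 ± 0.30 to 1.66 ± 0.35 FPKM and Vitvi04g00501 from 483 ± 1.7 to 92.7 ± 3.2 FPKM, log2 changes of -2.42 (SE 0.09) and -2.37 (SE 0.03). In all, 13010 genes were called by limma, 9404 higher and 3606 lower, with adjusted p of at most 7.12e-17 for the 4 named genes. The median log2 change of all genes was 0.14, and with median-of-ratios scaling it was -0.01 with 5903 genes called higher and 6135 lower. Quantile normalization gave 5624 and 6874 and TPM-like scaling 10545 and 3033, so the surplus of higher calls over all genes depended on the scaling. The surplus among genes changed 2-fold did not turn: 887 were higher and 327 lower with median-of-ratios scaling, and 805 and 333 with quantile normalization.

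PEG6000 raised 2882 genes at least 2-fold and lowered 1546. PT_newGene_31, a gene identifier of a second kind in the deposited table, increased from 0.439 ± 0.092 to 367 ± 4.9 FPKM (SD, n = 3; log2 change 8.00, SE 0.07), and PT_newGene_27 from 0.812 ± 0.12 to 323 ± 7.1 FPKM (log2 change 7.48, SE 0.08). Vitvi08g01454 fell from 322 ± 4.3 to 14.1 ± 1.3 FPKM and Vitvi02g01358 from 26.7 ± 1.3 to 0.408 ± 0.26 FPKM, log2 changes of -4.43 (SE 0.04) and -4.32 (SE 0.10). A set of 189 genes was below 1 FPKM in every control library and at 10 FPKM or more in every PEG6000 library, against 5 such genes under NaCl. The limma test called 15452 genes, 8533 higher and 6919 lower, and the adjusted p of the 4 named genes was at most 1.79e-21. With quantile normalization 6331 were called higher and 9556 lower, and the median log2 change of all genes moved from 0.05 to -0.14.

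**Figure D2:**
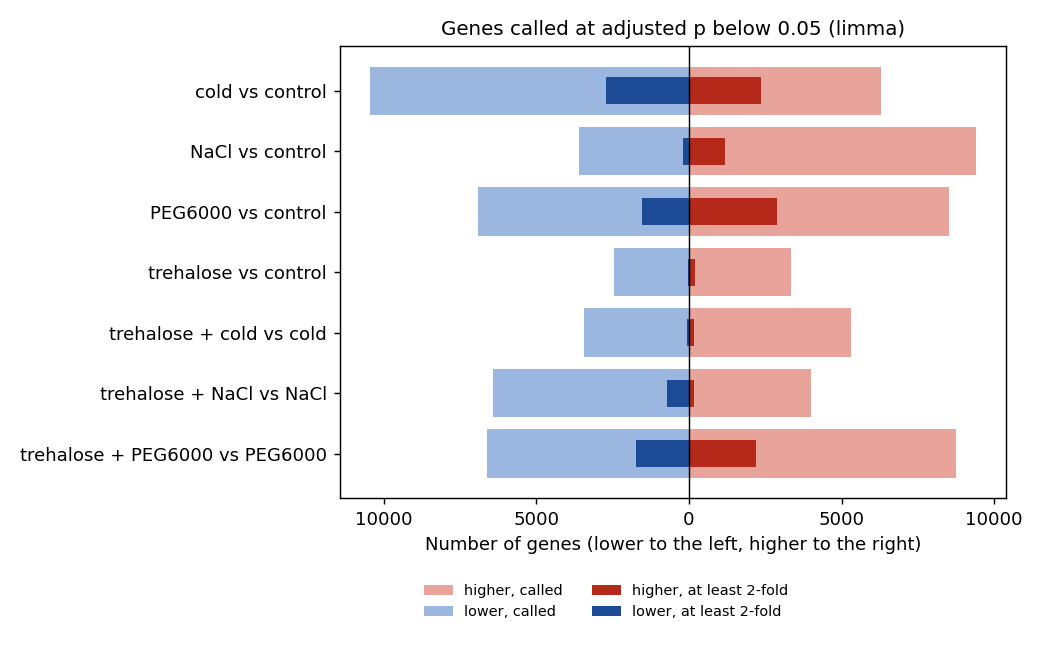
Number of genes (x axis) called higher (right) or lower (left) by limma at an adjusted p below 0.05 in the 7 main comparisons (y axis), with 3 libraries per group. Wide pale bars count all called genes and narrow dark bars those changed at least 2-fold on the log2(FPKM + 1) scale. Cold and PEG6000 changed 5076 and 4428 genes 2-fold, trehalose alone 227; the split of the pale bars into higher and lower depends on the scaling.

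A group of 517 genes rose at least 2-fold under all 3 stresses and 105 genes fell under all 3, where independent lists of these sizes would share 19.9 and 2.02. NaCl and PEG6000 raised 1020 genes in common (169 in independent lists), cold and PEG6000 1120 (339) and cold and NaCl 543 (139). Genes changed 2-fold in opposite directions numbered 5 for NaCl and PEG6000, 77 for cold and PEG6000 and 33 for cold and NaCl. Across genes, which are not independent replicates, the log2 changes correlated with Pearson's r of 0.76 (rho 0.74) for NaCl and PEG6000, 0.56 (rho 0.58) for cold and PEG6000 and 0.46 (rho 0.47) for cold and NaCl. All 3 effects are measured against the same control libraries, and unchanged groups simulated against those controls gave r of about 0.50, with 0.05 shared calls or fewer on average over 20 simulations. Such an r follows from a shared control wherever nothing else changes, however small the effects, so covariances are given as well. The covariances were 0.435, 0.650 and 0.263 for the same pairs, against simulated values of 0.0043. These values argue against the spread between control replicates as the source of more than a small part of the shared changes. A shift common to all 3 control libraries would not show in the simulations. Such a shift would set control apart from trehalose leaves too, and their root mean square log2 difference was 0.27. The distance from trehalose leaves was 1.12 for cold, 1.14 for PEG6000 and 0.63 for NaCl, against 1.07, 1.10 and 0.56 from control. These values argue against a shift of the control libraries alone as the main source. A shift shared with the trehalose libraries stays open. With 3 controls the control libraries cannot be divided into 2 sets of at least 2.

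Direct comparisons between stresses, which share no control, separated cold from both other treatments. Of the 2360 genes raised 2-fold by cold, 1622 (68.7%) were also higher in cold than in NaCl and in PEG6000 leaves, and of the 2882 raised by PEG6000, 2211 (76.7%) were higher than in both other stresses. Of the 1178 genes raised by NaCl, 173 (14.7%) exceeded both. Among lowered genes 2199 of 2716 (81.0%) were lower in cold than in both other stresses, 914 of 1546 (59.1%) in PEG6000 and 24 of 193 (12.4%) in NaCl. The genes were chosen from the same stress libraries, which raises all of these shares. The gap between cold and PEG6000 depended on the scaling. For raised genes the share of PEG6000 was the higher under all 4 scalings, by as little as 72.9 against 72.6% with median-of-ratios scaling. For lowered genes cold and PEG6000 had 72.5 and 72.3% with that scaling, and 67.3 and 68.8% with quantile normalization. NaCl stayed at 16.8% or less under every scaling. The limma test called 17143 genes between cold and NaCl, 16792 between cold and PEG6000 and 14490 between NaCl and PEG6000. Cold was the lower of the pair for 12790 and 11587 of these genes, and with median-of-ratios scaling for 7840 and 8154, the higher for 8108 and 8019; the median log2 difference of all genes moved from -0.37 to 0.01 and from -0.28 to -0.01. NaCl was the higher for 8495 and the lower for 5995 genes against PEG6000, and with that scaling for 6720 and 7382.

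Trehalose alone changed few genes strongly. It raised 205 genes and lowered 22 at least 2-fold. Vitvi04g00880 increased from 0.947 ± 0.29 to 23.5 ± 2.0 FPKM (SD, n = 3; log2 change 3.66, SE 0.14) and Vitvi01g04438 from 2.05 ± 0.40 to 24.3 ± 1.4 FPKM (log2 change 3.06, SE 0.12). Vitvi08g01702 fell from 15.98 ± 2.5 to 2.85 ± 0.78 FPKM and Vitvi02g00391 from 24.3 ± 3.6 to 6.94 ± 0.56 FPKM, log2 changes of -2.15 (SE 0.10) and -1.66 (SE 0.07), and both of these genes rose under each stress without trehalose. The limma test called 5818 genes, 3355 higher and 2463 lower, with adjusted p of at most 4.3e-14 for the 4 named genes. With median-of-ratios scaling 2911 were higher and 3309 lower.

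In the cold, trehalose left most of the response in place. Genes raised 2-fold by cold had a median log2 change of 1.72 without trehalose and 1.68 with it, relative to trehalose alone, and genes lowered 2-fold had -1.33 and -1.17. Of the 119 genes switched from below 1 to at least 10 FPKM by cold, 98 were at 10 FPKM or more in every library given trehalose with cold and 0 were below 1 FPKM in all of them. Set against cold alone, trehalose raised 170 genes and lowered 66 at least 2-fold. PT_newGene_2255 rose from 3.05 ± 0.23 to 40.2 ± 0.45 FPKM (log2 change 3.35, SE 0.07) and PT_newGene_38 from 2.46 ± 0.31 to 24.01 ± 0.53 FPKM (2.86, SE 0.07), while Vitvi17g01613 fell from 21.0 ± 0.80 to 3.35 ± 0.30 FPKM (-2.34, SE 0.08) and Vitvi17g04304 from 18.7 ± 1.0 to 3.33 ± 0.30 FPKM (-2.19, SE 0.08). The limma test called 8731 genes, 5306 higher and 3425 lower, with adjusted p of at most 4.77e-16 for the 4 named genes. With median-of-ratios scaling 4342 were higher and 5094 lower.

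Of the 2360 genes raised 2-fold by cold, trehalose moved 959 (40.6%) back and 488 (20.7%) further away. Of the 2716 lowered genes it moved 1478 (54.4%) back and 92 (3.39%) further. Moved back means called in the direction opposite to the stress effect, which does not exclude genes that passed their control level. The shifts were small, with median log2 changes of -0.11 and 0.22 in the 2 sets. With median-of-ratios scaling 1444 of 2993 raised and 911 of 1830 lowered genes were moved back.

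Under salt, trehalose was accompanied by a much smaller response. Of the 1178 genes raised 2-fold by NaCl, 1126 (95.6%) were lower in leaves given trehalose with NaCl than in leaves given NaCl, and of the 193 lowered genes 183 (94.8%) were higher. These counts depended on the processing: with pseudocounts of 0.1 and 0.01 the raised genes moved back numbered 1735 and 1733 and the lowered ones 333 and 361, and 316 of 327 lowered genes (96.6%) were moved back with median-of-ratios scaling and 321 of 333 (96.4%) with quantile normalization. Relative to control, the median log2 change of the raised genes went from 1.43 to 0.35, and 88 of the 1178 were still at least 2-fold higher. Vitvi14g02893, the gene with the largest rise under NaCl, fell from 139 ± 13 to 8.43 ± 0.93 FPKM (SD, n = 3; log2 change -3.90, SE 0.08) and Vitvi02g00393 from 114 ± 7.0 to 7.61 ± 0.30 FPKM (-3.74, SE 0.13). Vitvi05g01931 rose from 7.97 ± 0.86 to 80.7 ± 7.6 FPKM (3.19, SE 0.11), above its control level of 30.3 ± 1.1 FPKM, and Vitvi07g04602 from 0.875 ± 0.17 to 9.63 ± 1.4 FPKM (2.50, SE 0.14). The limma test called 10416 genes between the 2 groups, 3992 higher and 6424 lower with trehalose, with adjusted p of at most 5.66e-13 for the 4 named genes. With median-of-ratios scaling 4998 were higher and 5152 lower, and with quantile normalization 5783 and 4627.

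Under PEG6000 trehalose moved more genes than under the other stresses, 3936 at least 2-fold. Of the 2882 genes raised 2-fold by PEG6000, 2683 (93.1%) were lower with trehalose, and of the 1546 lowered genes 1503 (97.2%) were higher. These counts depended on the processing. The raised genes moved back numbered 1664 at a mean of at least 5 FPKM, which tests fewer genes, and the lowered ones 2345 with a pseudocount of 0.01. Relative to control, the median log2 change of the raised genes went from 1.81 to 0.68, and 915 were still at least 2-fold higher. Relative to trehalose alone, 345 of the 1546 lowered and 61 of the 2882 raised genes were called in the direction opposite to the PEG6000 effect. Of the 189 genes switched on by PEG6000, 58 were below 1 FPKM in every library given trehalose with PEG6000 and 2 were at 10 FPKM or more in every one. Vitvi18g02709 was at 129, 123 and 116 FPKM in the PEG6000 libraries, and with trehalose it was at 0.0600 FPKM in 1 library and listed at 0 in the other two (log2 change -6.92, SE 0.12). Vitvi05g02249 was at 151, 167 and 149 FPKM, and with trehalose at 2.31 FPKM in 1 library and listed at 0 in the other two (-6.71, SE 0.61). Both genes are listed at 0 in every control library. Vitvi07g02362 rose from 1.37 ± 0.23 to 274 ± 7.9 FPKM (6.86, SE 0.07), far above its control level of 2.07 ± 0.21 FPKM, and Vitvi02g01358 from 0.408 ± 0.26 to 83.1 ± 1.9 FPKM (5.92, SE 0.10) against 26.7 ± 1.3 FPKM in control. The limma test called 15341 genes, 8735 higher and 6606 lower, with adjusted p of at most 5.59e-10 for the 4 named genes. With median-of-ratios scaling 7090 were higher and 7958 lower, and at 2-fold 1841 and 1960, where the main scaling gave 2191 and 1745. More genes stayed higher than lower with TPM-like scaling (9052 and 6286) and quantile normalization (7888 and 7015).

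The counts of genes moved back by trehalose share the libraries of the stress alone, which makes opposite signs more frequent. Among all called genes, 5911 moved the opposite way to the effect of cold and 1863 the same way, 8250 and 430 for NaCl, and 11694 and 1234 for PEG6000. Independent lists would hold 1075 genes higher under cold and then lower with trehalose, where 2212 were seen, 3013 for NaCl with 5743 seen, and 2811 for PEG6000 with 5907 seen. For genes lower under the stress and then higher the counts were 3699 against 2765, 2507 against 718 and 5787 against 3014. In 20 simulations with the observed stress effects and no effect of trehalose there were 0 opposite calls. With no trehalose effect almost no gene can be called, so this value does not measure how far the shared libraries add opposite calls.

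Stress effects with trehalose, measured against trehalose alone, share no library with the effects without it and set cold apart from NaCl and PEG6000. Across 20053 genes the Pearson correlation between both effects was 0.94 for cold (rho 0.92), 0.55 for NaCl (rho 0.53) and 0.58 for PEG6000 (rho 0.52), with slopes of 0.93, 0.34 and 0.30. Of the genes raised 2-fold without trehalose, 1972 of 2360 were raised 2-fold with it for cold, 112 of 1178 for NaCl and 852 of 2882 for PEG6000. Of those lowered, 1789 of 2716, 44 of 193 and 68 of 1546 were lowered 2-fold with it. Genes are not independent replicates, so no p is attached to these correlations.

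**Figure D3:**
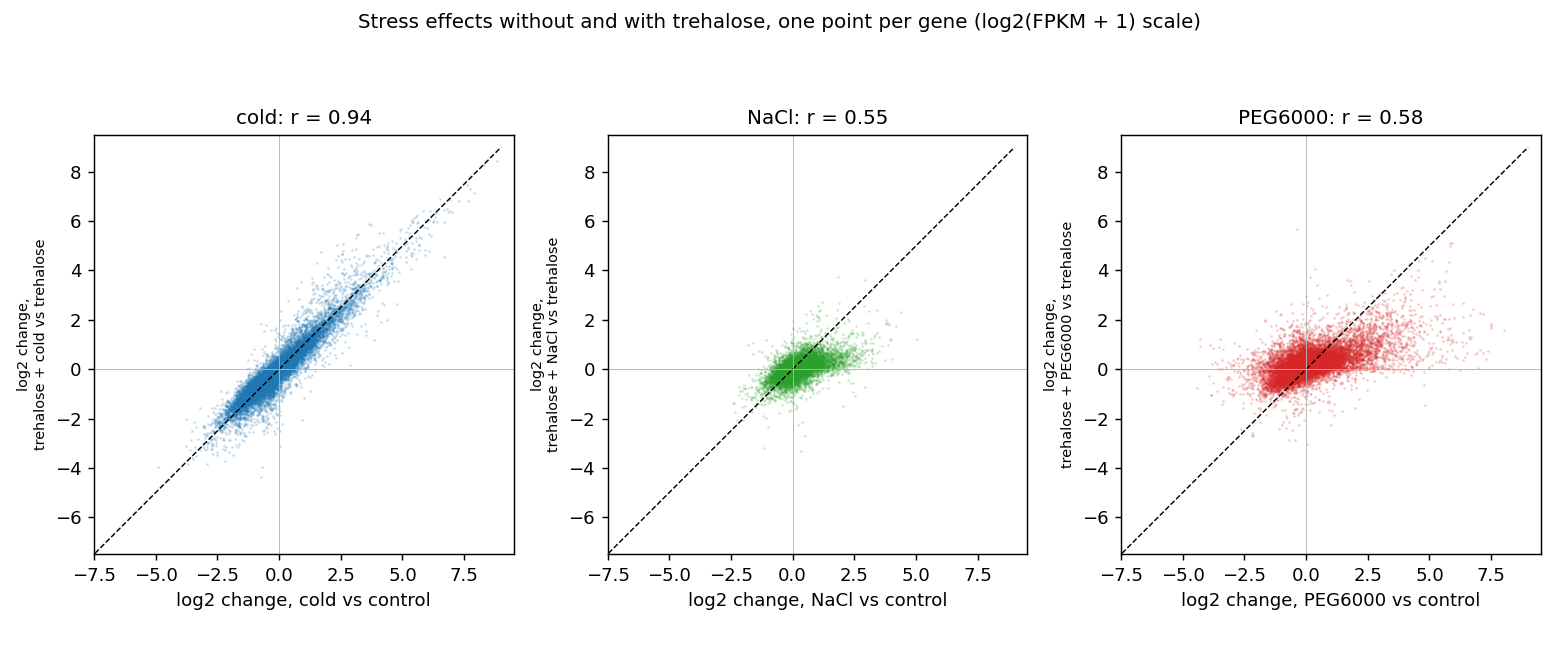
Log2 change of each of 20053 genes under a stress in leaves without trehalose (x axis) and with trehalose (y axis), on the log2(FPKM + 1) scale, for cold, NaCl and PEG6000. Each point is a gene and the dashed line marks equal changes. Points for cold follow the line (r = 0.94), and most points of genes changed by NaCl (r = 0.55) and PEG6000 (r = 0.58) lie nearer to 0 on the y axis.

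The effect of trehalose differed between stressed and unstressed leaves for 7137 genes under cold, 8616 under NaCl and 13529 under PEG6000, by the limma interaction test. At 2-fold or more the difference was positive for 201 genes and negative for 228 under cold, 97 and 825 under NaCl, and 1586 and 1778 under PEG6000, where TPM-like scaling gave 1960 and 1888. Of all genes called for cold, 3950 were positive and 3187 negative, with TPM-like scaling 3490 and 3661, and with median-of-ratios scaling 3597 and 3899. For PEG6000 they were 7673 and 5856, and with median-of-ratios scaling 6455 and 6731. Of all genes called for NaCl, 2859 were positive and 5757 negative, with median-of-ratios scaling 4148 and 4399, and with quantile normalization 4886 and 3997. Of the 205 genes raised 2-fold by trehalose alone, 74 were called higher with trehalose in the cold, 146 under NaCl and 178 under PEG6000. At 2-fold these counts were 10, 44 and 161, and 28, 20 and 18 of the 205 were called lower. Over all 20053 genes 5306, 3992 and 8735 were called higher. The median log2 changes of the 205 genes were 0.14, 0.53 and 1.69 against 1.23 without stress. For the cold interaction, 10 of 100 drawn splits of its 12 libraries, the real one included, called as many genes; the 9 others each set at least 4 more cold libraries on one side of the contrast than on the other, and of the 43 other splits with equal numbers, as in the real one, none called more than 135. Drawn splits mostly mix cold and other leaves within a group, unlike the real one, which enlarges the spread. Neither value therefore decides whether chance gives the real count.

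**Figure D4:**
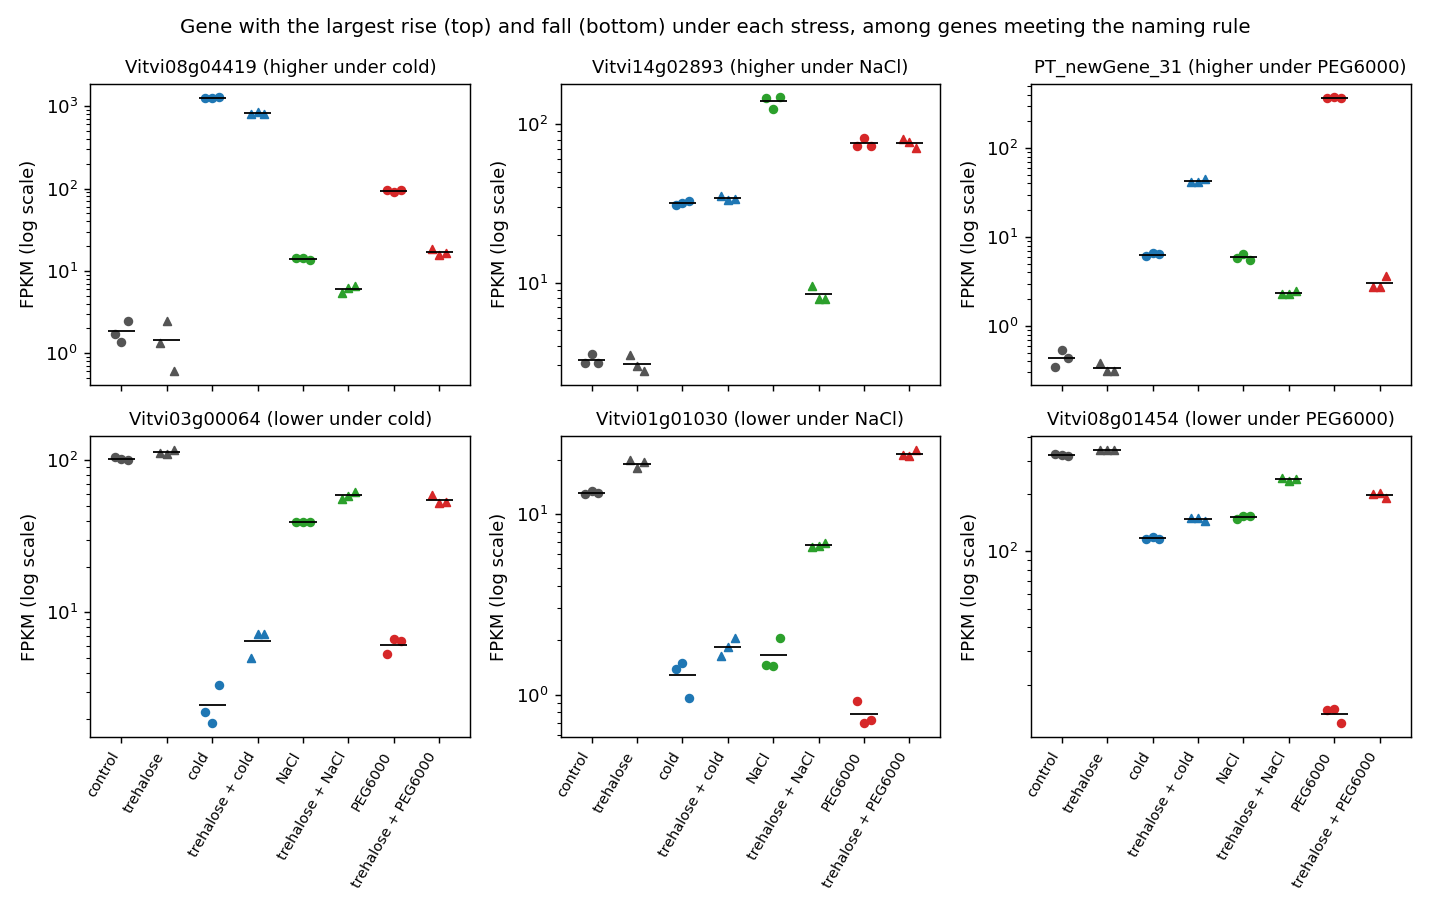
FPKM on a log scale (y axis) in each of the 24 libraries for the gene with the largest rise (top) and the largest fall (bottom) under cold, NaCl and PEG6000 among genes meeting the naming rule; points are libraries, bars are group means, and x gives the 8 groups. Vitvi14g02893 averages 139 FPKM under NaCl and 8.43 with trehalose and NaCl, but 75.7 and 76.5 under PEG6000 without and with trehalose.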

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

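The tests of a wrong label and of 1 factor for all genes, and the look at balanced splits, were chosen only after the results were seen; the other tests of this part were planned. The effect of trehalose differed between stressed and unstressed leaves, by the interaction test of limma at an adjusted p below 0.05, for 7137 genes under cold, 8616 under NaCl and 13529 under PEG6000. Other splits of the 12 libraries into 4 groups of 3 were drawn 100 times, the real split included. For cold, 10 of the 100 splits called as many genes as the real one, with up to 14735 in another split, so chance was not excluded by this test. For NaCl 2 of 100 splits did, the other with 8619 genes, and for PEG6000 1 split, the real one, with 12162 as the highest other. Both shares are under 0.05, but the drawn splits mix leaves that differ by stress and by trehalose. Their counts are thus not those of an absent interaction, and the test cannot exclude chance for NaCl or PEG6000. A split that calls 14735 genes, many more than the real one, points to a structure of the libraries: each of the 9 other splits that matched cold set cold libraries mostly on one side of the contrast, with an excess of at least 4 libraries. In the 43 other splits with equal numbers of cold libraries on both sides the highest count was 135. The same kind of split called up to 5570 genes for NaCl (43 splits) and 6303 for PEG6000 (44 splits), fewer than the real splits but not few. This look at balanced splits was not planned. Such splits mostly mix leaves with and without the stress within a group, which enlarges the spread. Their counts are therefore no measure of an absent interaction either.

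For the 2-group comparisons, 3 libraries against 3 make 10 splits, too few for a share under 0.05. In each of them the real split was the 1 with the highest count. Every other split puts libraries of both groups on each side, which enlarges the spread within a side. Counts near 0 therefore follow wherever the groups differ, and they do not measure what chance gives. The real counts and highest other counts were 16744 and 0 for cold, 13010 and 0 for NaCl, 15452 and 0 for PEG6000 and 5818 and 3 for trehalose, each against control. For trehalose with a stress against the stress they were 8731 and 0 (cold), 10416 and 0 (NaCl) and 15341 and 0 (PEG6000). Between stresses they were 17143 and 1 (cold and NaCl), 16792 and 0 (cold and PEG6000) and 14490 and 0 (NaCl and PEG6000).

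Of the genes named for trehalose alone, the interaction test separated its effect from that under stress as follows, on the log2 scale. Vitvi04g00880, raised by trehalose, had interactions of -3.62 with cold, -3.68 with NaCl and -1.07 with PEG6000, and Vitvi01g04438 of -3.24 with cold and -3.20 with NaCl. Vitvi08g01702, lowered by trehalose, had 2.09 with cold, 0.68 with NaCl and -1.43 with PEG6000, and Vitvi02g00391 had 1.74 with cold and -1.76 with NaCl. Among genes named for trehalose under cold, PT_newGene_2255 had 3.04, PT_newGene_38 had 2.76, Vitvi17g01613 had -2.39 and Vitvi17g04304 had -2.23. Under NaCl the values were 2.80 for Vitvi05g01931, 1.67 for Vitvi07g04602, -3.84 for Vitvi14g02893 and -2.45 for Vitvi02g00393. Under PEG6000 they were 6.05 for Vitvi07g02362, 5.54 for Vitvi02g01358, -6.92 for Vitvi18g02709 and -6.89 for Vitvi05g02249. Each gene was chosen for a large effect of trehalose with or without the stress. The interaction is built from these effects, so the choice favours large values. Vitvi18g02709 was listed at 0 in every control and trehalose library, so trehalose alone could not have lowered it.

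Salt and PEG6000 effects were smaller in leaves given trehalose. The scaling of the FPKM values is argued against, since under each of 3 other scalings at least 89.7% of the genes changed 2-fold were moved back, in both directions and both stresses. Libraries of leaves given trehalose alone under a wrong label are argued against as well: at least 9940 genes were called between trehalose with NaCl or PEG6000 and trehalose alone, with 0 in any other split. The other splits mix both groups, so the argument rests on the 9940 genes and not on the 0. The same response reduced on the log2 scale by 1 factor for all genes is argued against for both stresses: whichever factor was taken, at least 52.6% of the genes changed 2-fold by NaCl and 71.5% of those changed by PEG6000 differed from it (limma, adjusted p below 0.05) under each of 4 scalings, and simulated effects that followed 1 factor gave 0%. This was the last of several forms of the test. An earlier one, the share of these genes called in the opposite direction with trehalose, gave at least 3.00% for NaCl, between the bounds set for it, and 7.66% for PEG6000, above them. A reduced stress in leaves given trehalose, a slower response seen at 1 time, or a lower dose reaching these leaves may each explain the pattern and cannot be separated here.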

How the results depend on the processing

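No alternative was added after the data were seen; the scaling without abundant genes serves only the test at the end of this part. Of 492 alternative values of 25 main results, all of them counts or correlations, 453 stayed within the limit and 39 moved past it. The limit was 1.5 times for a count and, for a correlation, its SD over sets of 1 library per group. Directions were not compared in this way, and the surplus of higher or lower calls turned with the scaling in several comparisons. Each of the 28 named gene changes kept its sign and call under all of its alternatives, 472 in all. These genes were chosen for large changes without overlap, which favours this outcome. Of 383 alternative values of 19 further counts, 36 moved by over 1.5 times. Leaving out 1 library at a time, in 582 fits of a result, moved none past these limits, and counts of called genes changed by -14.3 to 0.732%. The replicate numbers only name the samples: deviations of same-numbered libraries correlated from -0.095 to 0.088, and 4 of 24 libraries correlated best with their own number. With the replicate block the calls numbered 16732 for cold, 12957 for NaCl, 15440.0 for PEG6000 and 5749 for trehalose against control, and no count of calls in the 13 comparisons changed by more than 1.25%. The 4 alternatives for gene lists were not run, since no list could be matched. A 2-fold limit, which by construction keeps fewer genes, left 5076, 1371, 4428 and 227 genes for cold, NaCl, PEG6000 and trehalose against control, 236, 890 and 3936 for trehalose under cold, NaCl and PEG6000, 429, 922 and 3364 for their interactions, 4719 between cold and NaCl, 4932 between cold and PEG6000, and 2399 between NaCl and PEG6000; 83, 736 and 2538 genes were then moved the opposite way by trehalose under cold, NaCl and PEG6000. A mean of at least 5 FPKM, which tests fewer genes, gave 11129 calls for cold against control, 11284 against NaCl and 11158 against PEG6000, and 745 and 1664 genes raised by NaCl and PEG6000 and moved back. For genes moved back, the cause of the other changes was not tested: raised by NaCl, 1735 (pseudocount 0.1) and 1733 (0.01); lowered by NaCl, 333 and 361, and 316 with median-of-ratios scaling and 321 with quantile normalization; lowered by PEG6000, 2345 (0.01); raised and lowered by cold, 1444 and 911 with median-of-ratios scaling. The correlation of cold effects without and with trehalose was 0.935 and 0.923 with these pseudocounts, 0.938 without a filter and 0.950 at a mean of 5 FPKM; that of NaCl effects was 0.530, 0.4998 and, at 5 FPKM, 0.612, and that of PEG6000 effects 0.653 at 5 FPKM and 0.589 with median-of-ratios scaling. Depth is unknown, so the precision of low genes rests on the spread between 3 replicates alone.

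The test in this paragraph was chosen only after the result was seen. More genes were called lower than higher under cold and more higher than lower under NaCl, 37.6% and 72.3% higher. With median-of-ratios scaling the shares were 51.2% and 49.0%, but that scaling centres the changes and decides nothing; they were 41.18% and 44.999% with quantile normalization and 39.96% and 77.66% with TPM-like scaling. Libraries were scaled to the sum of all genes but the 10, 30 or 100 most abundant by their mean over all libraries. For cold, the share called higher was then at most 36.2%, further from equal numbers. These 100 genes held 26.8% of the FPKM in cold against 34.9% in control. A lost share would raise and not lower the other genes, so these genes are argued against as the cause for cold. Genes that gained share in cold were not left out as a set, so an effect of such genes stays open. For NaCl the share called higher came to 62.9% with the 100 left out, which leaves an effect of abundant genes open. A real shift of most genes cannot be separated from other causes without counts or added standards.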

Other observations

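The test of carry-over was chosen only after the result was seen; that of neighbouring genes was planned. Many genes that trehalose raised in the cold were genes that the stresses raised in leaves without trehalose. Of the 170 genes raised 2-fold by trehalose in the cold, 118 (69.4%) were raised 2-fold by PEG6000 against control, compared with 13.9% of other genes, an odds ratio of 14.1 (95% interval 10.03 to 19.9, Fisher's exact test) between comparisons that share no library; genes are not independent replicates. The other genes were not chosen for a response, so any responsive set could give a high odds ratio. The 66 genes that trehalose lowered 2-fold in the cold were not compared in this way. Both of them named above, Vitvi17g01613 and Vitvi17g04304, were also higher in every PEG6000 library than in any control library. The overlap was not particular to PEG6000. NaCl raised 74 of the 170 (43.5%) 2-fold, compared with 5.55% of other genes, an odds ratio of 13.1 (9.49 to 18.1), and 68 of the 74 were also raised by PEG6000. Cold itself raised 73 of the 170, in a comparison that shares the cold libraries. PEG6000 was the only stress to raise 30 of the 170, and 40 were raised 2-fold by none. Trehalose lowered 117 of the 118 genes under PEG6000, as it did 2683 of all 2882 genes raised by PEG6000 (93.1%), in a comparison that shares the PEG6000 libraries by which they were chosen. PT_newGene_2255, at 40.2 ± 0.45 FPKM in leaves given trehalose with cold, was at 3.05 ± 0.23 FPKM in cold, 220.3 ± 2.4 in PEG6000 and 3.84 ± 0.36 FPKM in leaves given trehalose with PEG6000 (SD, n = 3). The overlap with PEG6000 held for these strongly raised genes and not for the transcriptome as a whole, where the 2 effects correlated with r of -0.005.

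New gene identifiers were over-represented in the same set. The exact tests below treat genes as independent, which they are not, so their p-values may be too small. How these identifiers were derived is not given in the sources used here. If they came from these same libraries, genes expressed under a stress alone would be listed because they were high there. That would build in part of the excess among raised genes, and it was not tested. Of 475 tested PT_newGene identifiers 22 (4.63%) rose 2-fold with trehalose in the cold, against 148 (0.756%) of the others (odds ratio 6.37, Fisher's exact test, adjusted p 7.44e-10 over 7 comparisons), and 19 of the 118 genes above were of this kind. They were also more frequent among genes raised by PEG6000 (23.6% against 14.1%, adjusted p 2.23e-07) and NaCl (10.9% against 5.75%, adjusted p 3.88e-05), and not past the threshold for cold (14.9% against 11.7%, adjusted p 0.0519) or trehalose alone (1.26% against 1.02%, adjusted p 0.491) by the same exact test. Among genes raised by trehalose under PEG6000 (8.00% against 10.997%, adjusted p 0.0519) and under NaCl (0.211% against 0.879%, adjusted p 0.232) they were the less frequent, not past the threshold.

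Carry-over of PEG6000 library into the libraries of trehalose with cold is argued against as the whole cause of the overlap with PEG6000. It would raise all abundant PEG6000 transcripts by about the same share of their PEG6000 level, and the 118 genes rose by a median of 25.7% of it. Among 57 genes at 50 FPKM or more under PEG6000, below 2 in control and trehalose and below 20 in cold, 52.6% rose by less than 1/3 of that share, and the shares ran from -11.0 to 50.3%. Reads shared between near-identical genes could not be examined without sequences or names and stay open. A shift of cold leaves given trehalose towards part of the response to other stresses is a hypothesis that these data do not test.

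Genes with neighbouring identifier numbers changed together more often than in shuffled orders for 10 of 13 sets of genes changed 2-fold, those with at least 50 Vitvi identifiers in the 7 main comparisons. PT_newGene identifiers were left out of this test. In these 10 sets, adjacent pairs exceeded each of 1000 shuffles within an identifier prefix (permutation p 0.001, the smallest they can give), and the ratio of observed to shuffled pairs over all 13 sets was 1.40 at the lowest and 12.3 at the highest. The other 3 sets did not exceed every shuffle: genes lowered by NaCl had 4 pairs (ratio 2.05, permutation p 0.129), genes raised by trehalose 9 (4.39, p 0.0020) and genes lowered by trehalose in the cold 2 (9.05, p 0.032). Neighbours changed together in the 10 sets, and for the other 3, with so few pairs, this is left open. What neighbours share was not tested.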
